A study of Canis lupus familiaris with 12 samples.

How the data were processed

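The 12 libraries are poly(A) RNA of canine PBMCs, prepared with NEBNext Ultra II kits and sequenced on a NextSeq 500 with 75 bp paired ends, per the labels' protocols. The submitters' processing notes name the genome build CanFam3.1 and the tool bcl2fastq; the aligner and the counting tool are not given in the sources used here, nor is it stated whether counting used strand. Each deposited table lists 29822 Ensembl genes with coordinates, of which 17892 carry a symbol, 11930 only an identifier and 2003 a symbol numbered as 1 of several copies. Per the file headers, each table holds total and unique exon reads, intron reads and total gene reads as counts, and TPM and RPKM. The deposited TPM values follow from exon reads and exon length, with differences of at most 4.6e-07. The deposited RPKM values imply a denominator per library larger than the reads assigned to genes; neither the TPM nor the RPKM values, which are the authors' own normalizations, entered a test. Total exon counts, as deposited by the authors with no normalization, were used for the tests, except those on unique exon reads, total gene reads or intron reads, which are named where they are given.

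Groups and replicate numbers were taken from the titles. The tests, gene lists, rule for named genes and alternatives were chosen before the data were examined, except where a later choice is stated. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, genes kept by filterByExpr on the groups, robust quasi-likelihood F-test), with all 12 libraries and 4 group means in 1 model, and Benjamini-Hochberg adjusted p under 0.05 over the 13358 genes kept. Biological coefficients of variation were 0.422 in this model and 0.217 with the replicate number as a block. Fold changes are log2 with SE, and levels are counts per unit of library size (CPM) on TMM-scaled library sizes with SD. A gene with 0 counts in a group was compared with a floor of 3 counts over the group, and a ratio of 1 to 3 counts was given a 95% counting interval. Exon reads unique to a gene were 93.6 to 95.0% per library. Genes with less unique reads, such as FTL (24.1%), IFIT1 (78.0%), FDPS (82.8%), HSPA8 (87.2%) and MSMO1_1 (92.7%), share reads with copies and their values are uncertain to that extent.

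Genes were named by a rule: per comparison, the 8 largest rises and 8 largest falls among called genes with a symbol and a mean of at least 20 counts in the higher group; up to 4 members of each list described, by smallest unadjusted p; and HMOX1, ALAS1, FECH, TFRC, IL2RA, CD69, IL2, IFNG, TNF, IL10, IL6 and MKI67 whatever their result. Where fewer than 10 genes with a symbol were called, the rule took those of the blocked model, or the 5 smallest unadjusted p where neither called any. For ConA with ALA against ALA, genes named elsewhere were given. Some genes the rule took are not reported here. Gene lists were 37, on heme and iron, NRF2, T cell activation and cytokines, inflammation and interferon, cell cycle, energy metabolism, stress and sterols, and markers of blood cell types. Of these 36 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The metal response list had 4 tested members and has no list test. Lists were written from general knowledge, and several markers are also expressed by other blood cells.

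Whether the numbers pair the samples was checked from deviations from the group means. The 18 pairs of libraries with the same number correlated at 0.376 to 0.748 and pairs from different groups with other numbers at −0.498 to 0.206. Pairs within a group, whose deviations from their shared mean offset each other, were left out. The centering also ties the pairs kept, as a library's covariances with the libraries of another group offset each other. The 2 ranges are thus not independent. Every pair of the same number lay above the threshold of 0.1, and 12 of 12 libraries correlated best with their own number. ConA 2 also lay above it with untreated 3, ALA 3 and ConA+ALA 3 (0.115, 0.206 and 0.165). The pairing thus comes from the shared numbers in the titles and this check. A model with the number as a block was fitted as an alternative, and its value stands with the result where it changes the call of a named gene or of a list, or moves a count of genes or of passing list members by over 1.5 times. Counts adjusted over the list alone are without the block unless stated.

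The other alternatives were DESeq2 1.42.0 (Wald test), limma-voom, DESeq2-type size factors, no filter, a mean of at least 50 counts, unique exon reads, mitochondrial and hemoglobin genes left out, the compared groups only, and each library and each number left out in turn. Total gene reads and the blocked model without each number were added after the data were seen. Where a number is left out, 2 libraries per group remain. Figures and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

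The steps were tested on simulated data with the real library sizes. Levels came from the untreated means and number effects of the blocked model, and spread from its dispersions. For ConA and for ALA, 100 genes each were changed 2-fold and 100 changed 4-fold among 13358. They were drawn from genes with a simulated mean of at least 5 counts. As the data followed the blocked model, its higher recovery was partly built in. Without the block the share recovered at 2-fold and 4-fold was 1% and 39% for ConA against untreated, 5% and 47% for ALA against untreated, 5% and 44% for ConA with ALA against ConA, and 2% and 40% for ConA with ALA against ALA, with 0 unchanged genes called. With the block it was 49% and 71%, 50% and 83%, 45% and 80%, and 48% and 69%, with 7, 5, 11 and 4 unchanged genes called. For the interaction no change was simulated, and 0 genes were called without and 1 with the block. A planted list in ALA against untreated gave p = 1.1e-11 at the preset and 7.5e-05 at the estimated correlation, and 3 and 0 of 200 random lists had an unadjusted p under 0.05. These lists held randomly chosen genes, so lists whose members vary together were not simulated and these rates do not cover them.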

Results

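The series measured messenger RNA in peripheral blood mononuclear cells (PBMCs) of dogs after 24 h in culture. The cells came from healthy male beagles kept as blood donors and were isolated on a density gradient. They were cultured with no addition, with 5-aminolevulinic acid (ALA, the precursor from which cells build heme) at 1.0 mM, with concanavalin A (ConA, a plant lectin that activates T cells) at 0.5 µg/ml, or with both. Each of the 4 groups holds 3 libraries numbered 1 to 3, 12 in all. Exon reads in libraries 1, 2 and 3 numbered 15972543, 15131294 and 17962226 in untreated cells, 17943837, 15320738 and 15144586 with ALA, 21517099, 17200099 and 16189125 with ConA, and 19355701, 15696611 and 13390692 with ConA and ALA. Between 11856 and 12917 genes had at least 10 reads. The labels do not state that the numbers are separate animals, so p-values measure the spread between these samples, which may be technical. In the model without the block this spread includes the differences between numbers, and the pairing by number is not used. The biological coefficient of variation was 0.422 there and 0.217 with the block.

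Libraries differed by number as well as by treatment. On the plot of principal components, the first (37.1% of the variance) separated cultures with ConA from those without, and the second (25.2%) separated number 1 from numbers 2 and 3. Mitochondrially encoded genes took 3.59 to 4.82% of exon reads in the 4 libraries of number 1 and 11.8 to 23.3% in the others. The share of reads spanning exon junctions was 52.4 to 54.2% in number 1 and 36.1 to 43.4% in the others. Each treatment group holds 1 library of each number, and the exact permutation tests of these measures between treatments (2-sided) gave p of at least 0.2, where 3 libraries against 3 cannot give less than 0.1. Within numbers, some measures moved the same way in 3 of 3. With ConA against untreated the mitochondrial share was higher (by 0.504, 10.6 and 4.11 percentage points in numbers 1, 2 and 3), and the intron share of gene reads and the count of genes with at least 10 reads were lower. With ConA and ALA against ALA these last 2 were lower too. With ALA against untreated the intron share was higher (by 1.44, 3.57 and 3.23 percentage points), and with ConA and ALA against ConA the exon reads were fewer. Exact sign-flip p was 0.25 in each, the smallest possible with 3 numbers.

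**Figure D1:**
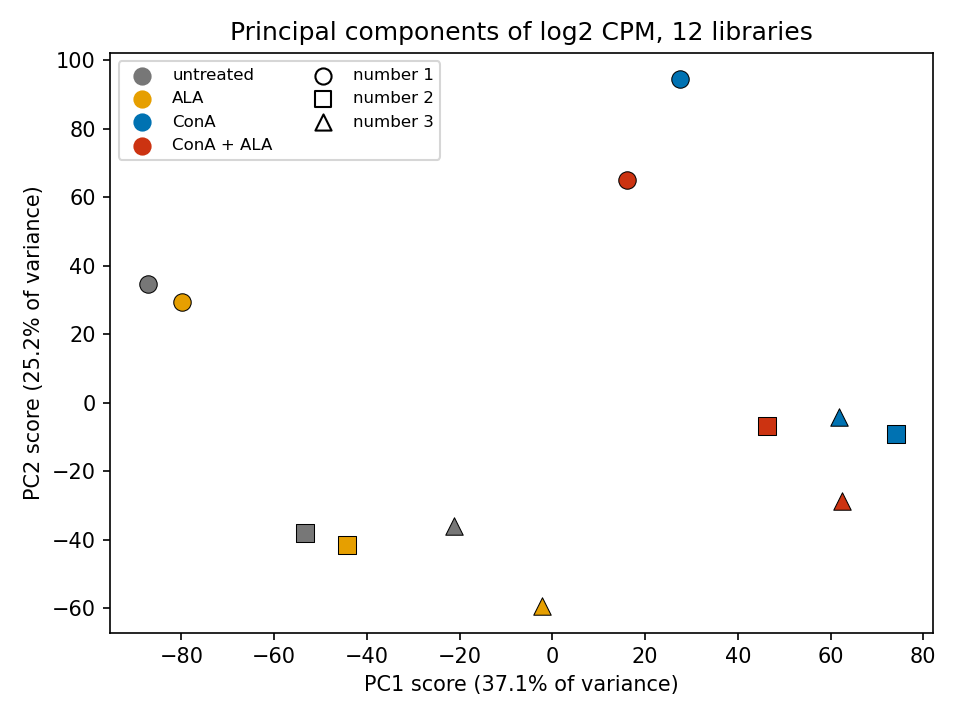
Principal components of log2 CPM for the 12 libraries, with the first component (37.1% of the variance) on the x axis and the second (25.2%) on the y axis. Colours mark the 4 groups and markers the 3 replicate numbers; ConA cultures lie apart along the first component and number 1 along the second.

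To describe how the cells responded to ConA, ConA cultures were compared with untreated ones (n = 3 each). IL2RA, the high-affinity chain of the interleukin-2 receptor (ENSCAFG00000005210, CanFam3.1 chromosome 2, 29894125 to 29944643, 11 annotated exons), rose from 12.9 ± 1.38 to 130 ± 36.8 normalised CPM (SD, n = 3), a log2 fold change of 3.33 ± 0.36 (SE, adjusted p = 0.00027). IFNG, encoding interferon gamma, rose from 2.08 to 78.8 ± 43.4 CPM (5.21 ± 0.86, adjusted p = 0.0022). IDO1 (ENSCAFG00000005750, chromosome 16, 25391754 to 25407048), a tryptophan-degrading enzyme, rose from 196 ± 149 to 1663 ± 268 (3.09 ± 0.45, adjusted p = 0.0011). Antiviral genes fell, among them OAS1 (−2.99 ± 0.48, adjusted p = 0.0016). In total 1326 genes rose and 1145 fell among 13358 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1831 of these 2471 changed at least 2-fold.

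**Figure D2:**
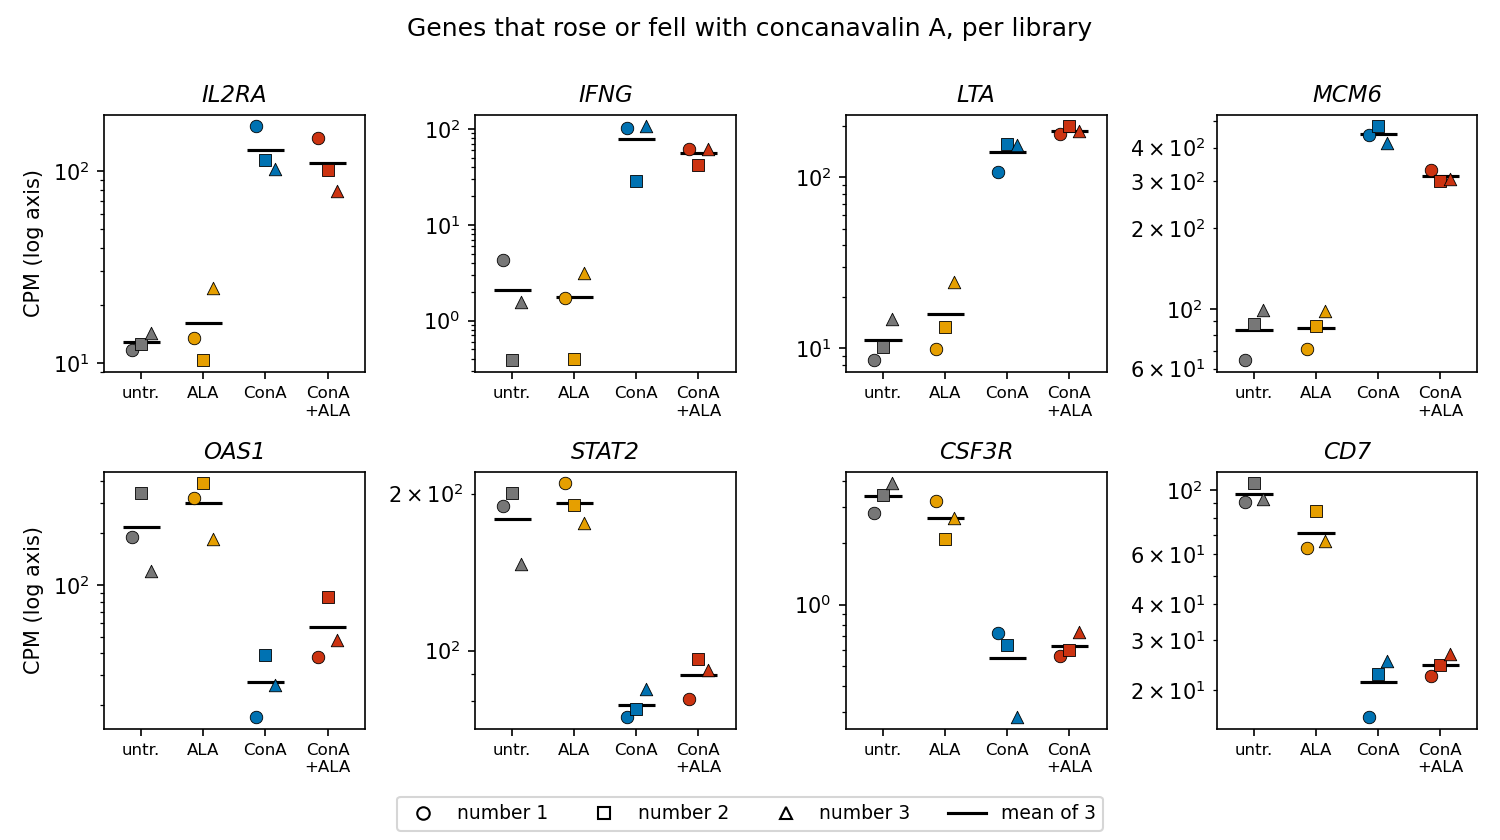
CPM (log axis) of IL2RA, IFNG, LTA, MCM6, OAS1, STAT2, CSF3R and CD7 in each of the 12 libraries, by group, with a line at the mean of 3 and markers for the replicate number. IL2RA rose from a mean of 12.9 in untreated cells to 130 with ConA, and OAS1, STAT2, CSF3R and CD7 were lower with ConA in all 3 numbers.

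The T cell activation list had 20 tested members, of which 13 rose and 0 fell (15 adjusted over the list alone). Its median log2 fold change was 1.74, above 0 in 18 of 20 (camera adjusted p = 1.6e-12, and adjusted p = 0.027 with an estimated correlation). NR4A3 (2.77 ± 0.25) and NR4A1 (3.28 ± 0.48), nuclear receptors induced by antigen receptor signalling, rose with the inhibitory receptor CTLA4 (1.93 ± 0.24). CD69, an early activation antigen, rose by 1.55 ± 0.38 (adjusted p = 0.015), a call lost without untreated 1 (adjusted p = 0.059). Of 17 T cell cytokine genes 8 rose and 0 fell (9 adjusted over the list alone), with a median of 2.08 (adjusted p = 2.3e-09, and adjusted p = 0.14 with an estimated correlation). LTA rose by 3.64 ± 0.35, IL21, a helper T cell cytokine, by 5.31 ± 0.69, LIF by 2.88 ± 0.46 and TNF by 2.57 ± 0.41 (adjusted p at most 0.0016 in each). IL2, the T cell growth factor, did not pass (1.81 ± 0.61, adjusted p = 0.058; DESeq2 called it, 0.013), nor did IL10 (−0.25 ± 0.45, 0.76) or IL6 (0.69 ± 1.02, 0.70).

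DNA replication genes rose nearly as a whole. Of 24 S phase genes 22 rose and 0 fell (22 adjusted over the list alone), with a median of 2.02 (adjusted p = 7.1e-25, and adjusted p = 0.027 with an estimated correlation). The list includes the replicative helicase subunit MCM6 (2.42 ± 0.22), thymidylate synthase TYMS (2.08 ± 0.22), the clamp loader subunit RFC4 (2.07 ± 0.23) and the ribonucleotide reductase subunit RRM2 (4.48 ± 0.53). Of 23 G2 and M phase genes 11 rose and 0 fell (14 adjusted over the list alone; 20 rose with the block), with a median of 1.61 (adjusted p = 4.8e-09, and adjusted p = 0.23 with an estimated correlation). CDK1 (2.27 ± 0.34), the cyclin CCNA2 (2.73 ± 0.48), CDC20 (1.97 ± 0.39) and topoisomerase TOP2A (2.71 ± 0.53) rose. The proliferation marker MKI67 did not pass (0.90 ± 0.91, adjusted p = 0.54) and passed with the replicate number as a block (1.45 ± 0.43, adjusted p = 0.029).

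The interferon response, monocyte and neutrophil lists were lower with ConA. Of 23 interferon response genes 19 fell and 0 rose (22 adjusted over the list alone), with a median of −1.61 (adjusted p = 1.8e-14, and adjusted p = 0.17 with an estimated correlation). Examples are the transcription factor STAT2 (−1.19 ± 0.18), IFIT1 (−3.05 ± 0.46) and IFIT3 (−2.63 ± 0.42), of which the last 2 overlap in the annotation, so their reads are partly uncertain. Of 14 monocyte markers 5 fell (6 adjusted over the list alone), with a median of −1.38 (adjusted p = 0.0015, and adjusted p = 0.37 with an estimated correlation), including the Fc receptor FCGR1A (−2.31 ± 0.45) and lysozyme LYZ (−4.06 ± 0.86). Of 10 neutrophil markers 4 fell (4 adjusted over the list alone), with a median of −1.83 (adjusted p = 0.00061, and adjusted p = 0.17 with an estimated correlation), including S100A8 (−1.67 ± 0.25) and the growth factor receptor CSF3R (−2.58 ± 0.49). With the block 11 monocyte and 7 neutrophil markers fell.

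Among T cell markers 5 of 16 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of −0.82 (adjusted p = 0.0026, and adjusted p = 0.46 with an estimated correlation). CD7 (−2.18 ± 0.21) and CD5 (−1.28 ± 0.20) fell and the costimulatory receptor CD28 rose (1.54 ± 0.36, adjusted p = 0.012). Of 11 B cell markers 2 fell (4 adjusted over the list alone), with a median of −1.13 (adjusted p = 0.026, and adjusted p = 0.54 with an estimated correlation). These were the kinase BLK (−1.19 ± 0.37, adjusted p = 0.044) and the antigen receptor chain CD79B (−1.31 ± 0.42, adjusted p = 0.049). Of the 12 fits that left out 1 library, BLK passed in those without ConA+ALA 1 or ConA 3 and CD79B in those without untreated 1, ALA 1, ConA+ALA 1 or ALA 2. The highest adjusted p were 0.14 and 0.20, both without untreated 2. Both passed with the block, in which 10 T cell and 9 B cell markers fell. The B cell list did not pass without ConA 1 or without untreated 2 (adjusted p up to 0.163 and 0.223).

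Chemokine genes rose, 7 of 11 (7 rose and 2 fell adjusted over the list alone; 7 rose and 1 fell with the block), with a median of 0.94 (adjusted p = 0.0023, and adjusted p = 0.23 with an estimated correlation). CCL22 (3.55 ± 0.65) and CCL20 (3.97 ± 0.88), ligands of lymphocyte chemokine receptors, rose with the interferon-inducible CXCL10 (2.14 ± 0.42). Of 18 inflammatory mediators 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.92 (adjusted p = 0.0015, and adjusted p = 0.23 with an estimated correlation). The gene that fell was IL12B (−6.06 ± 1.58, adjusted p = 0.020), a subunit shared by 2 monocyte-derived cytokines, a call lost without untreated 2, ConA 2 or ConA 3 (highest adjusted p 0.079). Among effector genes of killer cells, the granzyme GZMB rose (2.97 ± 0.54) and GZMK fell (−2.76 ± 0.36), and the cytotoxic effector list of 8 did not pass (median 0.37, adjusted p = 0.76; 3 rose and 1 fell with the block). The transcription factor TBX21, which directs interferon gamma production, rose by 2.90 ± 0.38 (adjusted p = 0.00064).

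The largest changes were in genes nearly silent in one group. GSDMC and EGR4 had 0 counts in untreated cells and were at least 36.8-fold and 21.2-fold higher with ConA against a floor of 3 counts over the group. The counts of IL9, a helper T cell cytokine, were 658 against 2 (ratio 343, 95% counting interval 94.5 to 2837), those of SH2D5 395 against 2 (206, 56.6 to 1706) and those of the B cell chemokine CXCL13 186 against 2 (96.9, 26.5 to 806). The secreted phospholipase A2 genes PLA2G5 (7.53 ± 0.84, adjusted p = 0.00029) and PLA2G2D (6.56 ± 1.31, adjusted p = 0.0053) rose. CD36, a scavenger receptor, fell from 38.6 ± 39.2 to 0.294 CPM (−6.88 ± 1.25, adjusted p = 0.0039). MEIOC fell from 176 counts to 1 (ratio 169, 29.9 to 6707), and DNASE1L3, a secreted nuclease, and DNAH5 were at least 36.8-fold and 24.0-fold lower. TMEM132C, DSCAM and HAS1 were at least 27.5-fold, 21.7-fold and 19.5-fold lower, and each lost its call without untreated 1, untreated 2, ConA 1, ConA 2 or ConA 3 (highest adjusted p 0.081, 0.076 and 0.10). HAS1 also lost it without ALA 2, untreated 3 or ConA+ALA 3. Intervals and floors cover counting error only.

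Lists of respiratory chain, ATP synthase, glycolysis and citric acid cycle genes were higher with ConA, though without the block most members of complexes I and IV, glycolysis and the citric acid cycle did not pass. With the block 21 complex I genes rose and 1 fell, 8 of complex IV rose, 9 of glycolysis rose and 4 fell, and 8 of the citric acid cycle rose. Of 11 genes of respiratory complexes II and III 8 rose (10 adjusted over the list alone), with a median of 0.79 (adjusted p = 9.8e-05, and adjusted p = 0.17 with an estimated correlation), among them cytochrome c, CYCS (2.01 ± 0.37), and UQCR10 (0.88 ± 0.16). Of 8 ATP synthase genes 6 rose (7 adjusted over the list alone), with a median of 0.97 (adjusted p = 0.00044, and adjusted p = 0.17 with an estimated correlation), including ATP5MC1 (1.34 ± 0.23). Of 28 complex I genes 7 rose (9 adjusted over the list alone; median 0.58, adjusted p = 0.00034, and adjusted p = 0.37 with an estimated correlation), and of 12 complex IV genes COX5A (1.34 ± 0.30) and COX7A2L (0.69 ± 0.22) rose (4 adjusted over the list alone; median 0.51, adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation). Of 20 glycolysis genes 5 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.020, and adjusted p = 0.37 with an estimated correlation). HK2, the first enzyme of glucose breakdown, rose by 3.43 ± 0.54 and ENO1 by 1.67 ± 0.20. Of 13 citric acid cycle genes 5 rose (5 adjusted over the list alone; median 0.62, adjusted p = 0.018, and adjusted p = 0.46 with an estimated correlation). Neither the glycolysis nor the citric acid cycle list passed without ConA 1 (adjusted p 0.0721 and 0.130) or without untreated 2 (0.0565 and 0.0503).

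The heat shock, integrated stress response and cholesterol synthesis lists were higher as well. Of 13 heat shock genes 9 rose (10 adjusted over the list alone), with a median of 1.33 (adjusted p = 8.3e-07, and adjusted p = 0.23 with an estimated correlation), including the chaperones HSP90AB1 (2.02 ± 0.24) and HSPH1 (2.19 ± 0.41). Of 19 integrated stress response genes 6 rose (9 adjusted over the list alone), with a median of 1.67 (adjusted p = 0.00086, and adjusted p = 0.10 with an estimated correlation). Asparagine synthetase ASNS (1.93 ± 0.34) and the serine pathway enzyme SHMT2 (2.65 ± 0.39), which also serve biosynthesis, were among them. Of 20 cholesterol synthesis genes 6 rose (11 adjusted over the list alone), with a median of 0.92 (adjusted p = 0.00020, and adjusted p = 0.23 with an estimated correlation), including FDFT1 (1.08 ± 0.17). With the block 11 integrated stress response genes rose and 1 fell, and 14 cholesterol synthesis genes rose.

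In the heme pathway, ALAS1, which makes ALA, stood at 1.29 ± 0.43 (adjusted p = 0.055) and passed with the replicate block (1.45 ± 0.37, adjusted p = 0.016), DESeq2 (0.012) and limma-voom (0.028). FECH, the last enzyme of heme synthesis (0.11 ± 0.30, adjusted p = 0.84), and HMOX1, which breaks heme down (−1.20 ± 0.48, adjusted p = 0.11), did not pass. The transferrin receptor TFRC rose by 2.39 ± 0.57 (adjusted p = 0.014), a call lost without ConA 1 (0.051) or untreated 2 (0.058). None of the 9 heme synthesis genes passed without the block (0 adjusted over the list alone; median 0.52, adjusted p = 0.11), and 4 rose with it. Of 8 porphyrin and peptide transporters 2 fell (2 adjusted over the list alone; median −0.63, adjusted p = 0.11), and with the block 4 fell and 1 rose. One was SLC15A1, a peptide transporter that also carries ALA, with 114 counts in untreated cells and 2 with ConA (ratio 54.7, 14.8 to 457).

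The number of calls depended on libraries and on the model. With the replicate number as a block, 2839 genes rose and 2837 fell. Without untreated 1 or untreated 2 the counts were 1592 and 1616. Without all 4 libraries of number 2 it was 55 and without those of number 3 1018. All 3 numbers showed the direction of every named gene that passed, which selection by a small p in the same libraries makes likely. Of the list calls, S phase and T cell activation held with an estimated correlation, and neither did with it and the block (adjusted p = 0.24 and 0.16).

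To describe ALA without ConA, ALA cultures were compared with untreated ones (n = 3 each). Genes of cell division, of the NRF2 antioxidant response and of cholesterol synthesis were higher with ALA as lists, while no single gene passed without the replicate block and 6 rose with it. All 23 G2 and M phase genes had a fitted fold change above 0, with a median of 0.79 (camera adjusted p = 8.4e-18, and adjusted p = 0.24 with an estimated correlation). Among them were the spindle factor TPX2 (1.57 ± 0.52), the centromere protein CENPA (2.51 ± 0.93) and the cyclins CCNB2 (2.31 ± 0.88) and CCNA2 (1.17 ± 0.47). Of 16 NRF2 targets 14 were above 0, with a median of 0.56 (adjusted p = 2.3e-14, and adjusted p = 0.24 with an estimated correlation), and 2 rose when adjusted over the list alone. The quinone reductase NQO1 stood at 1.75 ± 0.36, OSGIN1 at 1.18 ± 0.31, the cystine transporter SLC7A11 at 1.07 ± 0.43 and SQSTM1 at 0.81 ± 0.33. Of 20 cholesterol synthesis genes 18 were above 0, with a median of 0.35 (adjusted p = 2.2e-07, and adjusted p = 0.24 with an estimated correlation), including squalene synthase FDFT1 (0.51 ± 0.17) and INSIG1 (0.50 ± 0.17). These 3 lists passed in each of the 12 fits that left out 1 library. Without all 4 libraries of number 1, 5 of the 14 list calls of this comparison held.

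**Figure D3:**
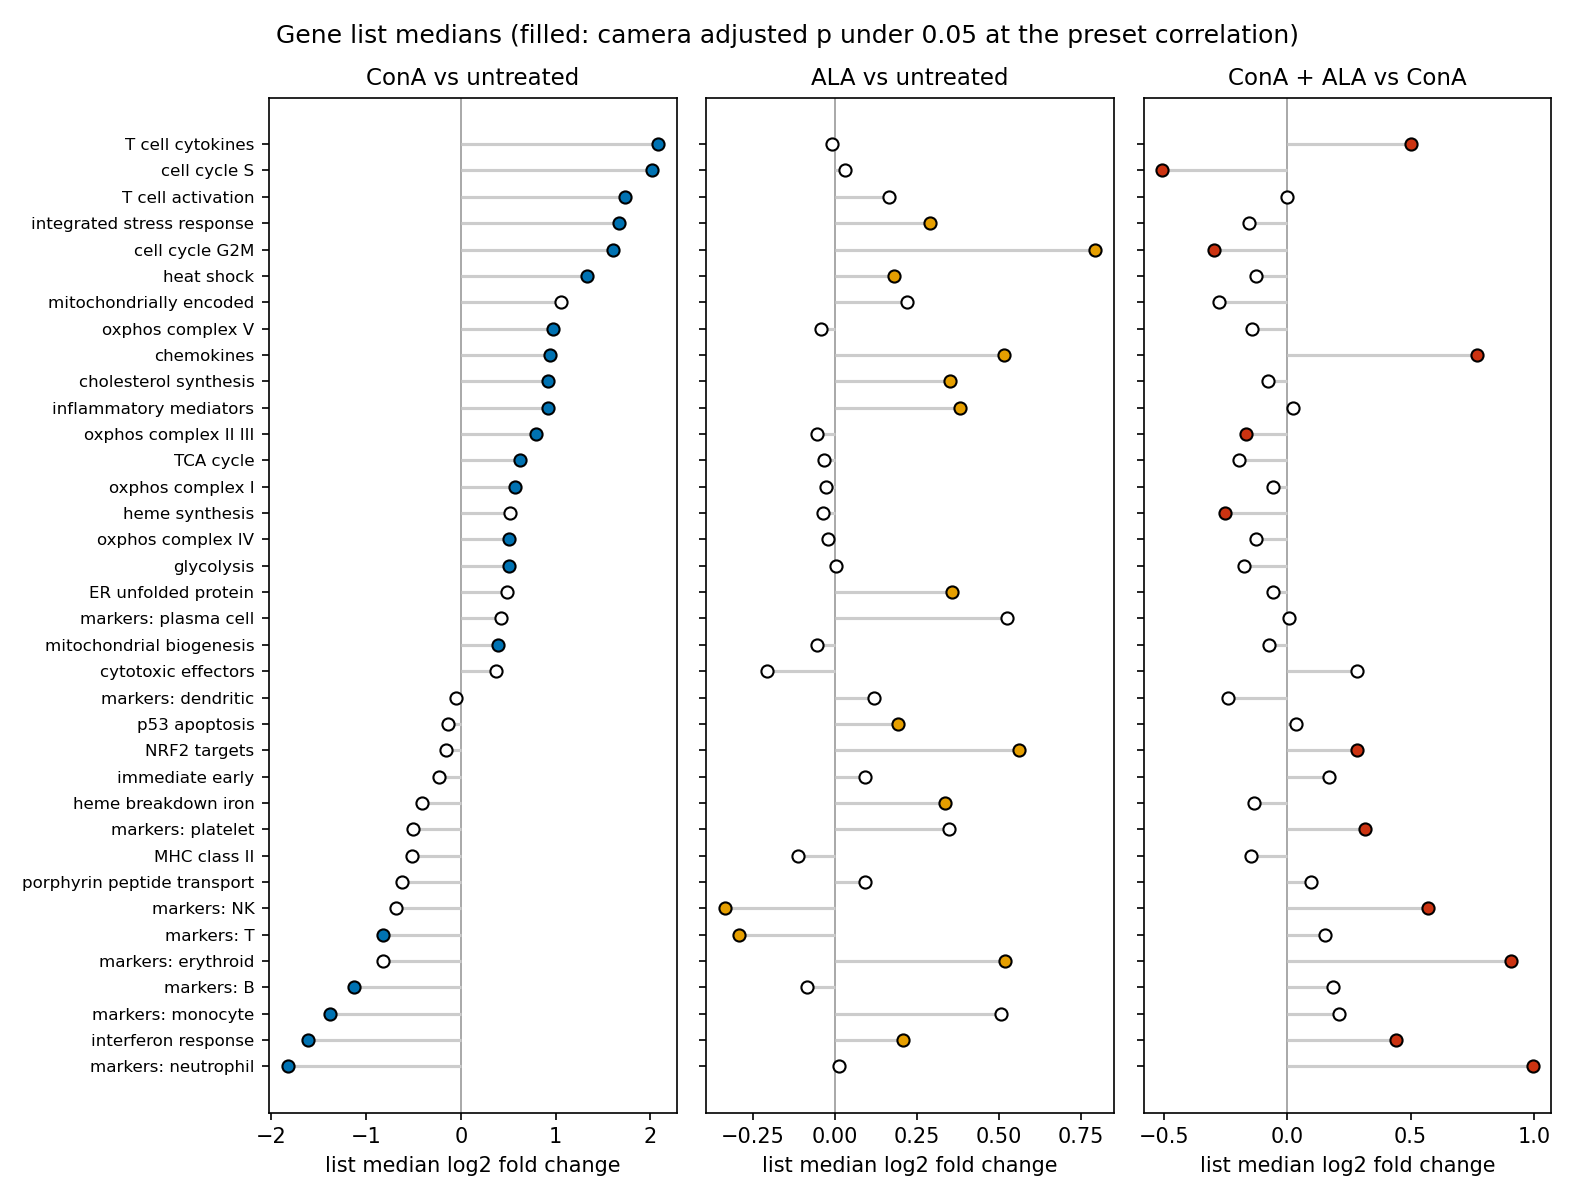
Median log2 fold change of the members of each gene list in 3 comparisons: ConA against untreated, ALA against untreated, and ConA with ALA against ConA, each panel with its own x axis. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation, such as S phase at 2.02 with ConA and G2 and M phase at 0.79 with ALA.

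The heme breakdown and iron list was above 0 in 11 of 14 genes, with a median of 0.34 (adjusted p = 0.0011, and adjusted p = 0.27 with an estimated correlation), and 1 gene rose when adjusted over the list alone. The biliverdin reductase BLVRA stood at 0.80 ± 0.22 and the ferritin chain FTL at 0.57 ± 0.27, of whose exon reads only 24.1% are unique to it. HMOX1 stood at 0.32 ± 0.48, ALAS1 at −0.87 ± 0.42, FECH at −0.04 ± 0.30 and TFRC at 0.01 ± 0.55, and the 9 heme synthesis genes did not pass (0 adjusted over the list alone; median −0.04, adjusted p = 0.40). All 14 genes of the endoplasmic reticulum list were above 0 (median 0.36, adjusted p = 0.00043, and adjusted p = 0.48 with an estimated correlation), including HSPA5 (0.46 ± 0.29). Of 23 interferon response genes 21 were above 0 (median 0.21, adjusted p = 0.0012, and adjusted p = 0.60 with an estimated correlation). The integrated stress response list had 15 of 19 above 0 (median 0.29, adjusted p = 0.015, and adjusted p = 0.24 with an estimated correlation), and the p53 list 9 of 13 (median 0.19, adjusted p = 0.015, and adjusted p = 0.24 with an estimated correlation). Heat shock genes had 9 of 13 above 0 (median 0.18, adjusted p = 0.022, and adjusted p = 0.64 with an estimated correlation) and inflammatory mediators 13 of 18 (median 0.38, adjusted p = 0.024, and adjusted p = 0.48 with an estimated correlation). Of 11 chemokines 7 were above 0 (median 0.51, adjusted p = 0.015, and adjusted p = 0.48 with an estimated correlation), a call lost with the block (adjusted p = 0.065). Red cell markers were above 0 in 8 of 10 (median 0.52, adjusted p = 0.017, and adjusted p = 0.48 with an estimated correlation). SLC15A1 went from 2.09 ± 0.853 to 18.6 ± 12.5 CPM (3.15 ± 0.83) and passed neither without nor with the replicate block (0.10).

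NK and T cell markers were lower with ALA as lists. All 9 NK cell markers were below 0 (median −0.33, adjusted p = 0.015, and adjusted p = 0.48 with an estimated correlation), including IL2RB (−0.43 ± 0.21). Of 16 T cell markers 2 were above 0 (median −0.29, adjusted p = 0.015, and adjusted p = 0.64 with an estimated correlation), with CD7 at −0.44 ± 0.20. The 11 B cell markers did not pass (median −0.08, adjusted p = 0.60), and passed toward lower without untreated 1 or ALA 2 and toward higher without untreated 2 (0.0128, 0.0263 and 0.0219). Without untreated 1 the T cell median was 0.12 and the NK cell median −0.0054 with a test toward higher (adjusted p 0.62 and 0.70). None of the members of these lists passed, also when adjusted over the list alone. With the block 2 T cell markers and 1 NK cell marker fell when adjusted over the list alone. Activation genes and cytokines did not pass. IL2RA stood at 0.32 ± 0.34, CD69 at 0.26 ± 0.37, IL2 at 0.05 ± 0.60, IFNG at −0.30 ± 0.80, TNF at −0.01 ± 0.40, IL10 at 0.26 ± 0.45, IL6 at 0.73 ± 1.02 and MKI67 at 1.03 ± 0.91.

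Of 13358 genes, edgeR's quasi-likelihood test called 0 for ALA against untreated, with 155 at an unadjusted p under 0.05 and a smallest adjusted p of 0.729. Chance alone would give 667.9, so the model without the block was conservative here and its 0 calls say little about the absence of an effect. limma-voom called 0 and DESeq2 4, which were NQO1 (1.77, adjusted p = 0.016), C6H7orf50 (1.06, adjusted p = 0.0017), PIR (1.33, adjusted p = 0.045) and a gene without a symbol that fell. PIR was chosen after its values were seen. With the replicate block 6 genes rose and 0 fell, all in 3 of 3 numbers: the growth arrest genes GADD45G (1.75 ± 0.25) and GADD45A (1.19 ± 0.18), the junction protein AFDN (1.71 ± 0.26), the collagen chain COL9A2 (1.44 ± 0.22), C6H7orf50 (1.05 ± 0.15) and the sterol oxidase MSMO1_1 (0.84 ± 0.13), with adjusted p from 0.028 to 0.033. Selection in the same numbers makes this shared direction likely. Without number 1, 2 or 3 in this blocked model the counts were 0, 0 and 18. Adjusted over the list alone, 6 NRF2 targets, 6 cholesterol synthesis, 4 G2 and M phase, 4 endoplasmic reticulum, 2 heme breakdown and iron, 2 chemokine, 1 heat shock and 1 p53 gene rose in the blocked model. List calls were lost without untreated 1 (inflammatory, chemokine, integrated stress, endoplasmic reticulum, p53, T and NK cell; adjusted p 0.0921 to 0.938), ALA 1 (heme breakdown, inflammatory, chemokine, interferon, integrated stress, heat shock, p53 and NK cell; 0.0610 to 0.642), untreated 2 (inflammatory, chemokine and heat shock; 0.0629 to 0.101), ALA 2 or untreated 3 (interferon, heat shock and erythroid; 0.187 to 0.354 and 0.178 to 0.955) and ALA 3 (inflammatory, chemokine, integrated stress, endoplasmic reticulum and T cell; 0.155 to 0.658). Without ALA 3 the medians of the endoplasmic reticulum and inflammatory lists were −0.024 and −0.036, and without untreated 3 the interferon test pointed toward lower. None of the list calls held with an estimated correlation.

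To describe ALA in stimulated cells, ConA with ALA was compared with ConA alone (n = 3 each). When the replicate number was a block, genes lower with ALA included the secreted phospholipases A2 PLA2G5 and PLA2G2F and the tryptophan-degrading enzyme IDO2, and genes higher included the chemokines CCL3 and CCL4. PLA2G5 (ENSCAFG00000023246, CanFam3.1 chromosome 2, 78762852 to 78781983) fell from 61.2 ± 51.6 to 1.52 ± 1.23 CPM (block −5.22 ± 0.38, adjusted p = 4.5e-05; −5.26 ± 0.73, adjusted p = 0.069 without it). Its neighbour PLA2G2F had 192 counts with ConA and 1 with ALA added (ratio 173, 95% counting interval 30.7 to 6866; block adjusted p = 0.012, 0.27 without it). IDO2, next to IDO1 on chromosome 16, fell by 3.05 on the log2 scale in the blocked model (SE 0.47, adjusted p = 0.0091; 0.16 without it). CCL3 (chromosome 9, 37686480 to 37695573), a chemokine of activated macrophages and T cells, rose from 107 ± 26.6 to 415 ± 34.6 (block 1.95 ± 0.24, adjusted p = 0.0068; 0.069 without it), and CCL4 rose with it (block 1.09 ± 0.15, adjusted p = 0.0053). CCL3 lies within the region of CCL4, so reads of the pair are partly uncertain. DESeq2 without a block called all 5.

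**Figure D4:**
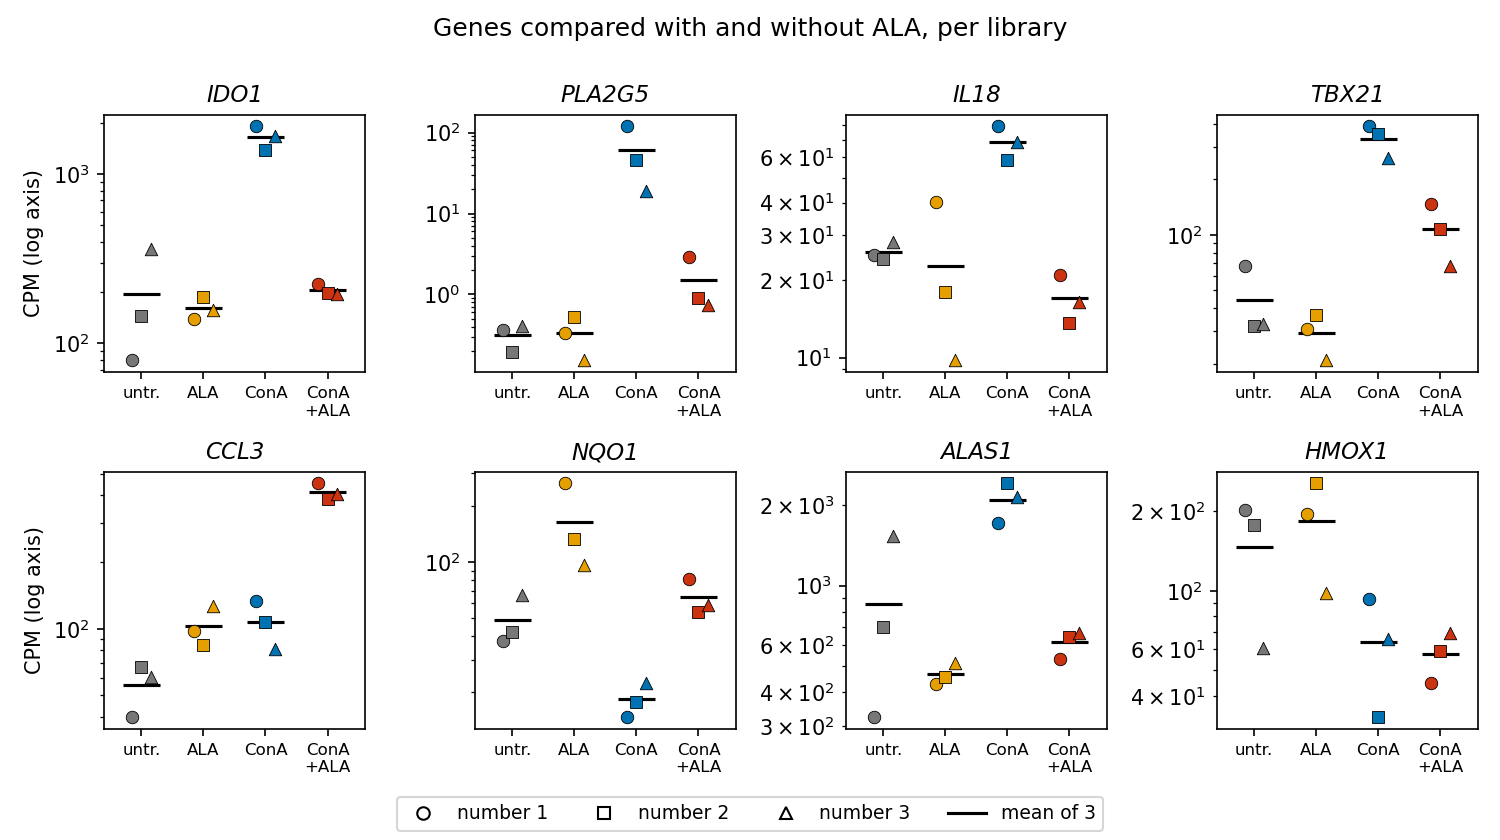
CPM (log axis) of IDO1, PLA2G5, IL18, TBX21, CCL3, NQO1, ALAS1 and HMOX1 in each of the 12 libraries, by group, with a line at the mean of 3 and markers for the replicate number. PLA2G5 had a mean of 61.2 with ConA and 1.52 with ConA and ALA, and CCL3 107 and 415.

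In the blocked model 45 genes rose and 29 fell. The largest falls included the complement component C1QB (−3.60 ± 0.64, adjusted p = 0.017), the lectin CLEC4G (−3.76 ± 0.78, adjusted p = 0.046), C1RL (−2.09 ± 0.40, adjusted p = 0.028), the inflammasome cytokine IL18 (−2.04 ± 0.34, adjusted p = 0.032) and the cholesterol exporter ABCG1 (−1.89 ± 0.36, adjusted p = 0.030). IL18 went from 68.9 ± 10.2 to 17.0 ± 3.64 CPM. TBX21 went from 331 to 108 (block −1.67 ± 0.19, adjusted p = 0.0032). The largest rises were in the protease inhibitor SERPINE2 (3.86 ± 0.56, adjusted p = 0.0091), the triglyceride synthesis enzyme GPAT3 (3.15 ± 0.58, adjusted p = 0.028), PPIC (2.91 ± 0.52, adjusted p = 0.017), FCGR1A (2.22 ± 0.32, adjusted p = 0.017), the tetraspanin CD9 (2.21 ± 0.25, adjusted p = 0.0032), BCHE (2.16 ± 0.46, adjusted p = 0.047) and PTHLH (1.84 ± 0.31, adjusted p = 0.015). S100A8 (0.90 ± 0.15), OSGIN1 (1.46 ± 0.29), GADD45A (1.15 ± 0.18) and GADD45G (1.18 ± 0.25) rose too. All of these moved the same way in 3 of 3 numbers, which their selection in the same numbers makes likely, and none passed in edgeR without the block. DESeq2 without a block called them except ABCG1, PPIC, BCHE, PTHLH, S100A8, GADD45A and GADD45G.

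IDO1 went from 1663 ± 268 to 207 ± 15.3 CPM, lower in 3 of 3 numbers, and passed in edgeR neither without the block (−3.01 ± 0.45, adjusted p = 0.10) nor with it (adjusted p = 0.069), while DESeq2 called it (adjusted p = 5.3e-09). PLA2G2D stood at −6.48 ± 1.31 (adjusted p = 0.27, block 0.060, DESeq2 0.022). ALAS1 went from 2085 ± 351 to 614 ± 71.6 (−1.76 ± 0.43, adjusted p = 0.56, block 0.12, DESeq2 0.014), and HMOX1 (−0.15 ± 0.48), FECH (−0.28 ± 0.30) and TFRC (−0.40 ± 0.54) did not pass. IL2 went from 15.7 ± 8.07 to 64.5 ± 31.9 (2.05 ± 0.60, adjusted p = 0.82, block 0.19). The other activation genes did not pass, with IL2RA at −0.24 ± 0.33, CD69 at 0.22 ± 0.37, IFNG at −0.51 ± 0.70, TNF at 0.05 ± 0.38, IL10 at −0.04 ± 0.46, IL6 at −0.00 ± 1.01 and MKI67 at 0.24 ± 0.90.

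As lists, S phase genes were lower and cytokine, chemokine, neutrophil and interferon genes higher with ALA. All 24 S phase genes were below 0 (median −0.51, camera adjusted p = 5.9e-10, and adjusted p = 0.18 with an estimated correlation), including POLA1 (−0.51 ± 0.19) and TK1 (−0.78 ± 0.31). Of 11 chemokines 7 were above 0 and 3 rose when adjusted over the list alone (median 0.77, adjusted p = 5.8e-06, and adjusted p = 0.21 with an estimated correlation), with CCL7 at 1.98 ± 0.44 (DESeq2 adjusted p = 0.0023) and CXCL10 at −0.99 ± 0.41. Of 10 neutrophil markers 9 were above 0 and 4 rose when adjusted over the list alone (median 1.00, adjusted p = 1.1e-05, and adjusted p = 0.18 with an estimated correlation), with MMP9 at 4.22 ± 1.41. Of 23 interferon response genes 20 were above 0 (median 0.44, adjusted p = 1.1e-05, and adjusted p = 0.53 with an estimated correlation). Of 17 T cell cytokines 14 were above 0 (median 0.50, adjusted p = 4.2e-05, and adjusted p = 0.34 with an estimated correlation), with CSF2 at 2.75 ± 0.83 and IL4 at 2.02 ± 0.83 but LIF at −0.87 ± 0.43. These 5 lists passed in each of the 12 fits that left out 1 library. In the blocked model, adjusted over the list alone, 10 S phase genes fell, 4 chemokines rose and 1 fell, and 6 neutrophil, 3 interferon response and 3 cytokine genes rose. The monocyte markers did not pass (median 0.21, adjusted p = 0.28, 1 rose adjusted over the list alone, 2 rose and 2 fell with the block), but passed without ConA 1 or ConA+ALA 3 (adjusted p 0.0342 and 0.0178).

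All 9 heme synthesis genes were below 0 (median −0.25, adjusted p = 0.010, and adjusted p = 0.18 with an estimated correlation), and ALAS1 fell when adjusted over the list alone. Of 16 NRF2 targets 12 were above 0 and 2 rose when adjusted over the list alone (median 0.28, adjusted p = 0.00041, and adjusted p = 0.46 with an estimated correlation), with NQO1 at 1.82 ± 0.37 (DESeq2 adjusted p = 0.0016). G2 and M phase genes had 3 of 23 above 0 (median −0.30, adjusted p = 0.0090, and adjusted p = 0.76 with an estimated correlation), with CDK1 at −0.83 ± 0.33. The NK cell list passed (median 0.57, adjusted p = 0.048, and adjusted p = 0.58 with an estimated correlation; 1 rose and 1 fell adjusted over the list alone) and did not with the replicate block (0.096). KLRD1 stood at 1.00 ± 0.33, against the fall of TBX21. Red cell markers had 8 of 10 above 0 (median 0.91, adjusted p = 0.00030, and adjusted p = 0.24 with an estimated correlation), and platelet markers 4 of 5, with 1 that rose when adjusted over the list alone (median 0.31, adjusted p = 0.010, and adjusted p = 0.26 with an estimated correlation). In the blocked model, adjusted over the list alone, 5 NRF2 targets rose and 1 fell, 6 NK cell markers rose and 1 fell, and 4 red cell and 2 platelet markers rose. The complex II and III list had 1 of 11 above 0 (median −0.17, adjusted p = 0.045, and adjusted p = 0.58 with an estimated correlation).

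List calls were lost without ConA 1 (heme synthesis, complex II and III, NK, platelet and erythroid; adjusted p 0.0594 to 0.304), ConA+ALA 1 (NRF2, G2 and M phase, complex II and III, NK; 0.10 to 0.821), ConA 2 (heme synthesis, NRF2, complex II and III, NK; 0.0645 to 0.588), ConA+ALA 2 (G2 and M phase, complex II and III, NK, platelet; 0.0544 to 0.116), ConA 3 (G2 and M phase, NK; 0.0577 to 0.285) and ConA+ALA 3 (heme synthesis, complex II and III, NK; 0.0569 to 0.290). The complex II and III and NK lists were also lost without untreated 2, ALA 2 or ALA 3 (0.0525 to 0.274), and the NK list without ALA 1 or untreated 3 (0.187 and 0.261). Of 13358 genes, edgeR's quasi-likelihood test without the block called 0 for ConA with ALA against ConA, with 445 at an unadjusted p under 0.05 (667.9 expected by chance). limma-voom called 0 and DESeq2 called 24 that rose and 25 that fell. Without untreated 1 the test called 6, without untreated 3 2 and without ConA 3 1. The blocked count of 74 was 23, 7 and 97 without number 1, 2 and 3. None of the list calls held with an estimated correlation.

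To compare stimulated with unstimulated cells in the presence of ALA, ConA with ALA was set against ALA alone (n = 3 each). IL2RA rose by 2.78 ± 0.35 (adjusted p = 0.0018), IFNG by 5.00 ± 0.86 (adjusted p = 0.0066), TNF by 2.63 ± 0.41 (adjusted p = 0.0037) and IL2 by 3.81 ± 0.65 (adjusted p = 0.0059), and OAS1 fell by 2.39 (SE 0.47, adjusted p = 0.0097). In all 680 genes rose and 405 fell. Of 17 T cell cytokines 11 rose (12 adjusted over the list alone; median 3.31, adjusted p = 2.7e-18, and adjusted p = 0.027 with an estimated correlation). Of 20 T cell activation genes 12 rose (15 adjusted over the list alone; median 1.64, adjusted p = 2.6e-16, and adjusted p = 0.019 with an estimated correlation), and of 24 S phase genes 15 (21 adjusted over the list alone; median 1.56, adjusted p = 5.3e-21, and adjusted p = 0.031 with an estimated correlation). These were the list calls that held with an estimated correlation, and none of them did with it and the block (adjusted p = 0.13, 0.071 and 0.23). Of 23 interferon genes 15 fell (20 adjusted over the list alone; median −1.78, adjusted p = 1.2e-18, and adjusted p = 0.14 with an estimated correlation). Of the 1326 genes that rose with ConA alone, 644 rose here (67.5 for independent lists), and of the 1145 that fell, 347 fell (34.7). Across genes, which are not independent replicates, the fold changes with and without ALA correlated at Pearson's r 0.760 and Spearman's rho 0.790, with no library shared. The count of 1085 was 435 without ALA 1, 456 without ALA 2, 519 without ConA+ALA 1, 464 without ConA+ALA 2 and 597 without ConA+ALA 3. With the replicate block it was 4022.

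The ALA effects with and without ConA were then set against each other. Across 13358 genes the fold changes correlated at Pearson's r 0.113 and Spearman's rho 0.032, with the same sign in 49.5%, and no library was shared. In the blocked model GADD45A and GADD45G rose in both (0.0202 genes for independent lists), and 0 genes fell in both. For genes that responded to ConA in the libraries of 2 numbers (blocked model), the median difference of ConA with ALA minus ConA was taken in the left-out number. It averaged −0.151 ± 0.073 for genes that rose with ConA and 0.210 ± 0.117 for genes that fell (log2, SD, n = 3), with exact sign-flip p = 0.25, the smallest possible. The direction was the same in 3 of 3 numbers. The test was planned without the block, but there number 2 had no responsive genes and number 3 had 16 and 9, so the blocked alternative stands in its place. With other size factors or a mean of at least 50 counts, number 3 had none either. In a later choice, responsive genes were taken without the block from all 8 libraries of the 2 numbers. The averages were then −0.206 ± 0.105 and 0.434 ± 0.356, with 42 and 13 genes for number 2.

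No gene passed the test of whether the ALA effect differed with ConA (edgeR's quasi-likelihood test, 0 of 13358, 222 at an unadjusted p under 0.05 where chance would give 667.9). With the replicate block 0 passed (1004 at an unadjusted p under 0.05, smallest adjusted p 0.105), limma-voom called 0 and DESeq2 4, which were PLA2G5 (−5.38, adjusted p = 0.0036), IDO1 (−2.76, adjusted p = 0.018), PLAAT3 (−1.80, adjusted p = 0.018) and a gene without a symbol. The 5 smallest unadjusted p, none of which pass, belonged to PLA2G2F (−7.15 ± 1.74), PLA2G5 (−5.33 ± 1.14), IDO1 (−2.74 ± 0.60), the phospholipase PLAAT3 (−1.78 ± 0.38) and the integrin ITGA7 (1.46 ± 0.35). Without untreated 3 IDO1 passed (adjusted p = 0.041). IL2 stood at 2.00 ± 0.84, ALAS1 at −0.89 ± 0.60 and HMOX1 at −0.47 ± 0.67. The remaining preset genes stood at −0.25 ± 0.43 (FECH), −0.41 ± 0.77 (TFRC), −0.56 ± 0.47 (IL2RA), −0.04 ± 0.52 (CD69), −0.20 ± 1.07 (IFNG), 0.05 ± 0.55 (TNF), −0.30 ± 0.64 (IL10), −0.73 ± 1.43 (IL6) and −0.80 ± 1.27 (MKI67). With the replicate block and number 1, 2 or 3 left out the counts were 0, 0 and 14.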

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

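The tests of technical explanations below were chosen after the results were seen, except that of NRF2 targets against random lists. The comparisons of intron reads were made on counts that no gene comparison of the report uses alone, and the tests of the interaction were planned.

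Several gene lists differed in their response to ALA between cells with and without ConA, by the test of the interaction itself. G2 and M phase genes had a median interaction of −0.99 on the log2 scale (camera adjusted p = 5.2e-16, and adjusted p = 0.36 with an estimated correlation), with CCNA2 at −1.93 ± 0.65 and TPX2 at −2.03 ± 0.72. S phase genes had a median of −0.55 (2.5e-09, and adjusted p = 0.35 with an estimated correlation), with RRM2 at −1.90 ± 0.66. Cholesterol synthesis genes had −0.42 (0.00060, and adjusted p = 0.54 with an estimated correlation), endoplasmic reticulum genes −0.41 (0.0081, 0.67), integrated stress response genes −0.50 (0.0085, 0.35) and heat shock genes −0.37 (0.047, 0.67), the last number in each being the adjusted p with an estimated correlation. NK cell markers had 1.01 (0.0014, and adjusted p = 0.38 with an estimated correlation), neutrophil markers 0.99 (0.0026, 0.36) with S100A8 at 1.08 ± 0.34, and T cell markers 0.50 (0.0090, 0.67). None of the members passed, also when adjusted over the list alone (in the blocked model 5 G2 and M phase genes, 1 cholesterol synthesis gene and 1 NK cell marker were then lower, and 5 NK cell and 2 neutrophil markers higher), and none of these 9 calls held with an estimated correlation.

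The S phase and the G2 and M phase lists passed in each of the 12 fits that left out 1 library, and the other 7 did not. Without all 4 libraries of number 1, 4 of the 9 list calls held. Calls were lost without untreated 1 (integrated stress, endoplasmic reticulum, heat shock, T and NK cell; adjusted p 0.0565 to 0.744), ConA 1 (heat shock and cholesterol; 0.700 and 0.0681), ConA+ALA 1 (endoplasmic reticulum, T and NK cell; 0.110 to 0.239), untreated 2 (endoplasmic reticulum and heat shock; 0.0678 and 0.0758), ConA 2 (heat shock and T cell; 0.0531 and 0.0790), ALA 3 (endoplasmic reticulum and T cell; 0.420 and 0.290) and ConA 3 (integrated stress, endoplasmic reticulum, T cell and neutrophil; 0.0536 to 0.0872). The heat shock list was also lost without ALA 1 (0.373), ALA 2 (0.159), untreated 3 (0.118) or ConA+ALA 3 (0.496). Of the lists not called, 15 passed without 1 library, in each removal but those of ConA+ALA 2 and ConA 3, among them T cell cytokines without ALA 3 (median 1.68, adjusted p = 1.5e-07) and mitochondrially encoded genes without ConA 1 (−0.99, 0.00063).

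Intron reads, which no gene comparison of the report uses alone, held signals in 4 comparisons. For ConA against untreated 1117 genes passed (637 rose and 480 fell among 15305 tested; 4980 with the replicate block). Of these 693 also passed in exon reads, 691 in the same direction, where independent lists would share 209. Intron and exon reads come from the same libraries, so calls shared between them are no separate support. For ConA with ALA against ALA 232 passed (3186 with the block), of which 142 also passed in exon reads. For ALA against untreated 0 passed (141 at an unadjusted p under 0.05, 5 with the block). For ConA with ALA against ConA 2 passed (edgeR's quasi-likelihood test, 409 at an unadjusted p under 0.05, 109 with the replicate block), and the same 2 genes passed in the interaction (2). They were TNFSF15, a tumour necrosis factor family cytokine (4.68 ± 0.39, adjusted p = 0.00056; interaction 3.82 ± 0.49), and IDO2 (−3.61 ± 0.34, adjusted p = 0.0012; interaction −3.47 ± 0.45, both interactions with adjusted p = 0.037). TNFSF15 was named after its values were seen. In exon reads TNFSF15 stood at 4.34 (adjusted p = 0.62) and IDO2 at −3.12 (0.16). In the blocked intron counts PLA2G5 (−4.81, adjusted p = 0.013), IL18 (−2.20, 0.015), NQO1 (1.92, 0.014) and CCL3 (1.75, 0.049) passed as well, and IDO1 (−2.48, 0.17), FCGR1A (2.01, 0.21), ALAS1 (−0.75, 0.51) and OSGIN1 (−0.20, 0.92) did not.

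The first pattern weighed is that genes that moved with ConA shifted back toward the untreated level with ALA. A uniformly weaker response to ConA would lower the T cell cytokines too, but their median difference was 0.72, 0.65 and 0.41, at its lowest 0.406. A scaling difference shared by all genes would move genes raised and lowered by ConA the same way. TMM scaling is meant to remove such a difference beforehand, and the medians over all genes were −0.0084, −0.00078 and −0.012 in numbers 1, 2 and 3. The medians of raised and lowered genes were −0.155 and 0.277, −0.222 and 0.278, and −0.076 and 0.075 (blocked model). They show no common shift left after the scaling, and cannot test a difference that the scaling removed. Differences in depth or scaling that act unequally on genes were not tested against the shift and stay open, as does chance, since 3 numbers cannot give a sign-flip p below 0.25. No biological explanation is put forward.

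The second is that IDO1, IDO2, PLA2G5, PLA2G2D, PLA2G2F, IL18, C1QB and CLEC4G were lower with ALA under ConA, of which IDO1 and PLA2G2D passed with DESeq2 but in neither edgeR model. Fewer monocytes would lower their markers by about as much, but the medians of the 14 monocyte markers were 0.35, 0.29 and −0.197 in the 3 numbers against −3.69, −3.56 and −3.31 for these genes (SD of the markers 0.947), and LYZ stood at 0.76 ± 0.78 (adjusted p = 1). The markers as a list thus did not fall by that much. ConA alone had already lowered them (medians −1.10, −1.67 and −1.72 against untreated in numbers 1, 2 and 3), which may leave less room for a further fall. With the block some of the markers rose with ALA under ConA and others fell. The list may follow cell state as well as cell number and cannot tell them apart. The 8 genes were chosen for their falls, so the gap was partly set in advance. A loss of monocytes, or of a small subset of them, stays open. Reads shared between copies are argued against by the share of unique exon reads, 100% in the lowest of the 8 genes. A weaker response to interferon gamma cannot be told apart: 15 inducible genes, a list written after the values were seen, had medians of −0.11, −0.11 and −0.335, but ConA itself had not raised them (median 0.06, SD 1.20), so the list could not show it. An effect of ALA on a subset of myeloid cells may be considered, as a hypothesis from the same data.

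The third is that NRF2 targets were higher with ALA with and without ConA. The medians over 16 genes were 1.00, 0.77 and −0.02 in numbers 1, 2 and 3 for ALA, and 0.17, 0.61 and 0.31 under ConA. A requirement set first, that all 6 lie above 0, was not met, and the one used instead was written after these values were seen. It asked that the second-highest median, 0.773 and 0.306, exceed the SD between numbers (0.537 and 0.226), which it did. Being set on these values, it is no separate support. The medians themselves show more than 1 number above 0 in both comparisons, and leave open that number 3 took no part without ConA. A trend with expression level is argued against, since 0 of 10000 random lists matched on mean expression had a median as high in either comparison (95th percentiles 0.114 and 0.094). An NRF2 response to ALA may be a hypothesis from the same data, except in number 3 without ConA, and was not tested further.

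Other splits of the libraries were fitted in the same way. For ConA against untreated 1 of 10 splits, the real one, gave a count as large (2471, highest other 0), as did 1 of 10 for ConA with ALA against ALA (1085, highest other 0). For ALA against untreated and for ConA with ALA against ConA all 10 of 10 gave 0. At an unadjusted p under 0.05 the real splits held 155 and 445 genes and others up to 1381 and 1717. These splits are too few for a share under 0.05. For the interaction the real count was 0, without and with the replicate block, so all 60 of 60 splits reach it whatever the data and say nothing about chance. The highest of them gave 2070, which points to a structure of the samples: it set all 4 libraries of number 1 against all 4 of number 3, and parted those of number 2 by ConA. With the replicate block, the real split and the highest of the others that part all 3 pairs gave 5676 and 1, 6 and 0, 74 and 0, and 4022 and 0 in the order of the comparisons. Only 4 splits per comparison part all 3 pairs, the real one included, again too few for a share under 0.05. The others mix the 2 treatments, so that a treatment effect adds to their spread, and their low counts are no support for the real ones.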

How the results depend on the processing

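Total gene reads and the blocked model without single numbers were chosen after seeing the data. Over 31 settings, 10377 values kept their side of the threshold, 316 of them with the other sign where neither value was called. Many were called in neither fit, such as 998 values of named genes in ALA against untreated, so this count does not measure how well calls held. Of 78 genes named for ConA against untreated that passed, 64 passed in all 12 single-library removals, 78 with the replicate block, 78 with DESeq2, 71 with limma-voom and 12 without number 2. Without number 1, 18 of 21 list calls held for ConA against untreated, 9 of 12 for ConA with ALA against ConA and 18 of 22 for ConA with ALA against ALA. For the interaction 4 of 9 held. For ALA against untreated 5, 12 and 13 of 14 held without number 1, 2 and 3, and 9 with total gene reads. Depth limits genes near the floor of 3 counts, for which only bounds were given. The setting with only the compared groups was not run for the interaction. The cause was not tested for any value below except where fewer libraries remain.

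For ConA against untreated 2471 genes passed. Alternatives gave 5676 with the replicate block, 1614 with only these groups, 1592 to 2467 over single-library removals, 55 without number 2 and 1018 without number 3. For ALA against untreated 0 became 6 with the block, 4 with DESeq2 and 0, 0 and 18 with the block without number 1, 2 or 3. For ConA with ALA against ConA 0 became 74 with the block, 49 with DESeq2 (28 of them also called with the block), 2 with no filter (CCL3 and IDO1), 3 with only these groups (SERPINB2, IDO1 and SAA1_1), 2 with gene reads (TNFSF15 and IDO2), and 23, 7 and 97 with the block without number 1, 2 or 3. Single removals gave 0 to 6, with IDO1 and SAA1_1 without untreated 3, PLA2G5 without ConA 3, and PLA2G5, CCL3 and CCL7 without number 1 (3). These genes were chosen after their values were seen. For ConA with ALA against ALA 1085 became 4022 with the block, 1830 with DESeq2, 435 to 1184 over single removals, 0 without number 2, 137 without number 3, and 2096, 2157 and 3817 with the block without number 1, 2 or 3; the blocked ConA counts without them were 3627, 3794 and 5418. For the interaction 0 became 4 with DESeq2, 1 (IDO1) without untreated 3 and 0, 0 and 14 with the block without number 1, 2 or 3. The correlation of ALA effects, 0.113, was 0.123 with the block, 0.112 with other size factors, 0.109 without mitochondrial and hemoglobin genes and 0.198 with a mean of at least 50 counts.

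In ALA against untreated, 8 lists had a test toward the other side after a removal, where 1 of the values compared had passed. T cell cytokines ranged over removals from −0.293 without ALA 3 to 0.594, inflammatory mediators from −0.082 without number 1 to 0.665 (−0.053 with the block without number 1), and mitochondrially encoded genes from −0.438 without ALA 3 to 0.691, with −0.218 without untreated 1. Interferon genes ranged from 0.077 without untreated 3, with a test toward lower, to 0.465. T cell markers ranged from −0.493 to 0.121 without untreated 1, B cell markers from −0.421 to 0.514 without untreated 2, and NK cell markers from −0.572 to −0.0054 without untreated 1, with a test toward higher. Monocyte markers ranged from −0.495 without ALA 1 to 0.716, with −0.360 without number 1 and −0.347 with the block without number 1. Where the test kept its side, medians of the other sign included −0.024 without ALA 3 for the endoplasmic reticulum list and −0.0061 with the block without number 3 for red cell markers in ALA against untreated, −0.021 with gene reads for p53 targets in ConA with ALA against ConA, and in the interaction 0.71 without ALA 1 for monocyte and 0.099 without ConA+ALA 1 for platelet markers. Apart from the calls given beside their results, the block also changed list calls for glycolysis (0.036), citric acid cycle (0.036) and B cell markers (0.0021) in ConA with ALA against ConA, for cytotoxic effectors (0.018), mitochondrially encoded genes (0.0064) and B cell markers (0.021) in ConA with ALA against ALA, and for cytotoxic effectors (0.023), mitochondrially encoded genes (0.037), B cell markers (0.0098) and plasma cell markers (0.0076) in the interaction, all to passing, and none of these held with an estimated correlation (adjusted p at least 0.277); it changed no other list call.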

Other observations

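The list results below were planned, and no test in this part was chosen after the results were seen. Lists not yet described for ConA against untreated were mostly small or mixed. Of 11 mitochondrial biogenesis genes 3 rose (3 adjusted over the list alone; median 0.39, adjusted p = 0.035, and adjusted p = 0.23 with an estimated correlation), namely the mitochondrial transcription factor TFB2M (1.45 ± 0.18), the DNA-binding protein SSBP1 (1.28 ± 0.19) and PPRC1 (0.86 ± 0.18). The list did not pass with the replicate block (0.074), without ConA 1 or without untreated 3 (0.0628). All 13 mitochondrially encoded genes were above 0 (0 rose, 0 adjusted over the list alone; median 1.05, adjusted p = 0.12), and the list passed with the block (0.00083, and adjusted p = 0.45 with an estimated correlation), without ConA 1 (0.0014) or without untreated 3 (0.047); all 13 genes rose with the block. The endoplasmic reticulum list was above 0 in 14 of 14 with 1 that rose, MANF (1.25 ± 0.39; 0 adjusted over the list alone; median 0.49, adjusted p = 0.050), and passed with the block (0.0075, and adjusted p = 0.45 with an estimated correlation) and with limma-voom (0.018); 8 genes rose with the block. It also passed without ConA 1, untreated 3 or any 1 of the ALA and ConA+ALA libraries (adjusted p at most 0.0476).

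Of 16 NRF2 targets 2 rose and 2 fell with ConA (2 and 2 adjusted over the list alone; median −0.16, adjusted p = 1.0), with TXNRD1 and ESD higher and NQO1 (−1.41 ± 0.36) and OSGIN1 (−1.45 ± 0.32) lower. Among 14 heme breakdown and iron genes TFRC rose and BLVRB fell (−1.45 ± 0.28; 1 and 1 adjusted over the list alone; median −0.41, adjusted p = 0.31). NK cell markers had 1 that rose, TBX21, and 3 that fell, with KLRD1 at −1.59 ± 0.33 (1 and 3 adjusted over the list alone; median −0.68, adjusted p = 0.32). Dendritic cell markers had 2 that rose, with the transcription factor BATF3 at 3.79 ± 0.60, and 1 that fell (2 and 1 adjusted over the list alone; median −0.05, mean 0.11, adjusted p = 0.42). Red cell markers (2 fell, GYPC and KLF1; median −0.83, adjusted p = 0.12), platelet markers (GP6 fell; −0.50, 0.22), MHC class II genes (DLA-DOA fell; −0.52, 0.22), immediate early genes (ZFP36 fell; −0.23, 0.39), p53 targets (MDM2 rose and SESN1 fell; −0.13, 0.58) and plasma cell markers (0 changed; 0.42, 0.39) did not pass as lists. The counts adjusted over the list alone were 2, 1, 1, 1, 1 and 1, and 0. With the block 5 NRF2 targets rose and 4 fell, 2 heme breakdown and iron genes rose and 3 fell, 5 NK cell, 2 dendritic, 5 red cell and 5 MHC class II genes fell (1 MHC class II gene rose), 3 immediate early genes fell, 2 p53 targets rose and 3 fell, and 3 plasma cell markers rose. Red cell markers passed without ConA 2 (0.025) and plasma cell markers without untreated 3 (0.038).

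With ALA alone, plasma cell markers (median 0.52, adjusted p = 0.065), porphyrin and peptide transporters (0.09, 0.076; 1 rose adjusted over the list alone) and MHC class II genes (−0.11, 0.097) did not pass, and passed with the replicate block (1.5e-06, 0.025 and 0.016, and adjusted p = 0.32, 0.28 and 0.58 with an estimated correlation). Plasma cell markers also passed with limma-voom (0.049). In the blocked model 1 plasma cell marker rose and 1 cytotoxic effector fell when adjusted over the list alone. T cell activation genes (0.16, 0.070), T cell cytokines (median −0.01, mean 0.38, 0.17), monocyte markers (0.51, 0.19), S phase genes (0.03, 0.24), cytotoxic effectors (−0.21, 0.31) and dendritic markers (median 0.12, mean −0.10, 0.96) did not pass. Of the 22 lists not called, 12 passed without 1 of untreated 1, untreated 2, untreated 3, ALA 1, ALA 2, ALA 3 or ConA+ALA 1, the lowest adjusted p being 5.5e-06 without untreated 3. With ALA added to ConA, 24 lists did not pass, among them T cell activation (median −0.00, adjusted p = 0.97), cholesterol synthesis (−0.08, 0.73), inflammatory mediators (median 0.02, mean 0.18, test toward lower, 0.90), heme breakdown (median −0.14, mean −0.07, test toward higher, 0.94), integrated stress response (−0.16, 0.28) and heat shock genes (−0.13, 0.48). Of these 24, 8 passed without 1 of ConA 1, ConA+ALA 1, ConA 2, ConA 3 or ConA+ALA 3, such as heat shock genes without ConA 3 (0.038) and mitochondrially encoded genes without ConA 1 (0.00021, the lowest). With ConA and ALA against ALA, 22 lists passed, including chemokines (6 rose, 7 adjusted over the list alone; median 1.53, adjusted p = 8.3e-07, and adjusted p = 0.14 with an estimated correlation), and monocyte markers were lower (1 fell, 11 with the block, 9 adjusted over the list alone; median −1.80, 0.00013, and adjusted p = 0.29 with an estimated correlation). Of the 22, 7 did not pass without 1 library, in each removal but those of untreated 1 and untreated 3 (adjusted p up to 0.356), and B cell markers and mitochondrially encoded genes, not called, passed without ConA+ALA 2 or ALA 1 (0.012 and 0.026) and without ConA+ALA 1 or ALA 3 (0.0079 and 0.024).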
